A study of Mus musculus with 4 samples.

How the data were processed

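RNA of 4 samples of mouse cells was measured on Affymetrix whole-transcript arrays: LMPPs (1 array), Tcf1 cells (2 arrays) and control cells (1 array). The RNA was amplified with the Ambion WT Expression kit and labelled with the Affymetrix WT Terminal Labeling kit, per the labels' protocols. RMA and Partek 6.5 made the values, per the submitters' processing notes, which state no parameters. The values deposited by the authors are log2 signal per probe set; the base is not stated and was taken from RMA and from the range of 3.44 to 14.45 over the arrays. The genome build is not given in the sources used here. Scanner files and detection calls were not used here, so signal over background was judged only by array quantiles: the 5th percentile of genes lay between 4.68 and 4.80 on the 4 arrays and the 95th between 11.04 and 11.20.

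Of 35399 probe sets, 21789 carried a single gene symbol, 1621 several and 11989 none, so 38.4% had no single name and were left out of the gene tests. Symbols were checked against a gene table through Entrez numbers, which covered 21698 probe sets and renamed 0. For the 999 genes with several probe sets, the probe set with the highest mean over the arrays was used, which left 19938 genes. No filter on dim genes was applied. Genes of the lists without a single-gene probe set (29 of 359 entries, Tcf7 and Lck among them) are not analysed here.

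Tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Group means were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes, and genes passed at an adjusted p under 0.05. The fit had 1 residual degree of freedom, from the Tcf1 pair, and a prior of 5.78 degrees of freedom with an SD of 0.141, so 6.78 in all. The single LMPP and control arrays were assumed to vary as the Tcf1 pair did. Standard errors of differences come from this fit, and SDs of group means from the 2 Tcf1 arrays. In the text, "rose", "fell", "higher" and "lower" of genes in these comparisons refer to genes past this test unless a fold minimum is named. Control cells against LMPPs, 1 array against 1, had no test, and genes at least 2-fold apart were counted.

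Named genes are the 10 largest differences in each direction among genes past the test with both Tcf1 arrays on the same side and a mean in the higher group above the median gene, without predicted and clone-named genes. They also include the sort gate genes and up to 4 members of each list with the largest differences. Other list members named in the text were chosen after their values were seen. Trgv1 and Ly6a2 belong to families with shared sequence.

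The 18 lists were T lineage transcription factors, the T cell receptor complex and its signalling, antigen receptor recombination, Notch targets, Wnt/beta-catenin targets, cytokine and homing receptors, stem and progenitor genes, myeloid, B lineage, NK and innate lymphoid, dendritic cell and MHC class II, mast cell with basophil, erythroid and megakaryocyte, stromal, cell cycle, immediate early and heat shock, interferon response, gamma delta and alternative T cell, and sort gate genes. They were tested with limma cameraPR at a preset correlation of 0.01, adjusted over the lists. At this preset the members of a list count as nearly independent, and LMPPs and control cells had 1 array each. The list p-values therefore do not measure variation between preparations of cells, however small they are. The alternative with a correlation estimated from the residuals (limma camera) rests on 1 residual degree of freedom. Its smallest unadjusted p was 0.0811 against LMPPs (interferon list) and 0.0626 against control cells (myeloid list), so no list passed. It had too little power to decide whether a list was shifted, and its adjusted p-values are given for completeness. For control cells against LMPPs, list medians were ranked among 10000 random lists matched in 10 expression bins. A list of 15 macrophage markers was added later for a test of the closing section and has no list test. The shared LMPP reference was simulated 100 times with unchanged groups, and, added after the results were seen, so were the shares of genes whose 2 sides share the LMPP or the control array.

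The gene and list tests were tested on simulated data of this size, in 20 simulations with 200 changed genes each, for Tcf1 cells against LMPPs and against control cells in turn. With spreads drawn from the fitted prior, 51.1% and 44.4% of 2-fold changes and 99.6% and 99.3% of 4-fold changes were recovered, and 9.19% and 8.90% of called genes were false. With each gene's spread as fitted, 97.7% and 97.5% of 2-fold changes were recovered and 16.4% and 16.1% of called genes were false. The share of false calls was thus above the nominal 5% in both forms. Shifted lists were called in 20 of 20 simulations and unshifted lists in 0 of 340 by limma cameraPR. The simulated genes varied independently of each other, so these counts do not show how often lists of correlated genes would be called falsely.

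Alternatives covered the prior of the test, filters on dim genes, renewed quantile normalization, median centring, other treatment of several probe sets, other thresholds, the unmoderated test, the 3 T lineage arrays as a single group, each Tcf1 replicate left out and other forms of the list test.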

Results

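Transcript levels were measured in lymphoid-primed multipotent progenitors (LMPPs), a bone marrow population that can still form lymphoid and myeloid cells, and in T lineage cells grown from them in culture, all from C57BL/6 mice. Pooled LMPPs, sorted without lineage markers and with Sca1, Kit and a high level of Flt3, were measured on 1 array after 48 hours in the medium used for transduction. Cells positive for Thy1 and CD25 were sorted on day 10 from cultures of LMPPs given a retrovirus for Tcf1, the transcription factor encoded by Tcf7, and grown on OP9, a bone marrow stromal line without Notch ligand. They were measured on 2 arrays, labelled as biological replicates, and are called Tcf1 cells here. Cells of the same surface type and day, from LMPPs given the empty vector and grown on OP9-DL4, which presents the Notch ligand DL4, were measured on 1 array and are called control cells. The sort of both cultures removed dead cells and cells with the myeloid markers Mac1 or Gr1. Tcf1 cells and control cells therefore differed in vector and in stroma. Both differed from the LMPPs in time in culture, stroma, sort gate and, as far as stated, retrovirus. The effects of these on a difference from LMPPs cannot be told apart. Tcf7 had no probe set with a single gene name and is not analysed here, so the transduced gene could not be used to check the labels.

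The 4 arrays had median log2 values of 7.26 (LMPP), 7.27 and 7.29 (Tcf1 replicates 1 and 2) and 7.28 (control) over 35399 probe sets. Over the 19938 named genes, which the tests used, the medians lay further apart. They were 7.49 (LMPP), 7.47 and 7.59 (Tcf1 replicates 1 and 2) and 7.49 (control). The interquartile range over these genes was 2.91 in Tcf1 replicate 1 and lay between 3.13 and 3.22 in the other arrays. The number of arrays limits the precision. The Tcf1 replicates differed from each other with an SD of 0.24 on the log2 scale across genes, and 65 genes (0.326%) were at least 2-fold apart between them. LMPP and control arrays differed with an SD of 0.55, and 1102 genes (5.53%) were at least 2-fold apart. The closest arrays of different groups, LMPP and Tcf1 replicate 2, had an SD of 0.42, which was 1.78 times that of the replicate pair. This held for the named genes only. Over the 11989 probe sets without a gene symbol, the replicate pair had an SD of 0.55. There, Tcf1 replicate 2 was closer to the LMPP array (0.40) and to the control array (0.39) than to replicate 1.

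Tcf1 cells were compared with LMPPs to ask which genes differed between the input progenitors and the T lineage cells obtained with Tcf1 in the absence of a Notch ligand. Some genes for T lineage transcription factors and lymphoid receptors rose, and some for granulocyte proteins and progenitor transcription factors fell. Gata3, a transcription factor required for T cell development, rose by 2.54 on the log2 scale (SE 0.20, adjusted p = 0.00136, limma), from 7.58 in the LMPP array to 10.12 ± 0.24 (SD, n = 2). Bcl11b, needed for T lineage commitment, rose by 2.08 (SE 0.17, adjusted p = 0.0017, limma). Il7r, the receptor chain for the lymphoid cytokine IL7, rose by 2.95, and Txk, a kinase of T cell receptor signalling, by 3.49. Ngp, a neutrophil granule protein, fell by 3.73, and Elane, neutrophil elastase, fell by 2.53. Both Tcf1 arrays lay on the same side of the LMPP array for all of these genes.

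Among the genes with the largest increases, Trgv1 rose by 7.04 (SE 0.16), although this T cell receptor gamma segment shares sequence with its family and the signal could come from a relative. Il2ra, which encodes the sort marker CD25, rose by 6.07 (SE 0.16), and the sort marker Thy1 rose by 4.33 (SE 0.17), both as cells gated on these proteins. Vcan, the proteoglycan versican, rose by 5.05, Rhoj by 4.49, and Adgre1, a macrophage surface receptor, by 4.37. Rasgrp1, an activator of Ras below the T cell receptor, rose by 4.26, the interferon-induced gene Rtp4 by 4.15, F13a1, a coagulation factor subunit, by 3.85 and Psg17 by 3.83. The largest decreases were those of Adgrl4, an adhesion receptor, at -4.29 (SE 0.22), Ngp at -3.73, Gem, a small GTPase, at -3.71, and the carbonic anhydrase gene Car2 at -3.64. Angpt1, the secreted ligand angiopoietin, changed by -3.07, Spint1, a protease inhibitor, by -2.92, Kmo, an enzyme of tryptophan breakdown, by -2.85, Scin, an actin-severing protein, by -2.85, Nrp1, a co-receptor, by -2.75, and Ccnd1, cyclin D, by -2.71. Standard errors of these 20 differences ran from 0.16 for Nrp1 to 0.35 for Scin.

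T lineage groups moved unevenly between LMPPs and Tcf1 cells. Of 22 measured T lineage transcription factors, 5 rose, 1 fell and 16 did not pass, and adjusted over the list alone 6 rose and 2 fell. Besides Gata3 and Bcl11b, Ets1 (1.95), Lef1 (1.75) and Ikzf2 (1.30) rose, and Ets2 fell by 1.06. The list test pointed up and passed (adjusted p = 5.4e-05, limma cameraPR), with adjusted p = 0.778 with an estimated correlation. The median was 0.10, or 0.15 after renewed quantile normalization and 0.06 after median centring. The mean was 0.40, so some members carried the shift rather than the list as a whole. Of 24 genes of the T cell receptor complex and its signalling, 6 rose, 3 fell and 15 did not pass (8 and 4 adjusted over the list alone). Txk, Trat1 (2.69), Cd247 (1.66) and Cd2 (1.52) rose, while Cd96 (-2.10), Cd28 (-1.52) and Cd5 (-1.48) fell. Cd3e (0.11) and Cd3d (0.16), chains of the CD3 complex, did not pass, and Cd3g rose by 0.94. The list median was 0.18, or 0.12 after renewed quantile normalization (adjusted p = 1.3e-04, and adjusted p = 0.729 with an estimated correlation). No gene of the 9 of antigen receptor recombination passed, alone or over all genes, with 1 up and 1 down at an unadjusted p under 0.05 in limma. Its median was -0.05 (adjusted p = 0.999) and turned to 0.08 after renewed quantile normalization and to 0.04 with replicate 2 alone, and Rag1 differed by 0.51 and Rag2 by -0.66.

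Of 16 Notch target genes, 2 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone. The risers were Il2ra and Cd3g, and Dtx4 fell by 1.16. Hes1 (-0.18), Dtx1 (-0.05) and Nrarp (-0.52), which Notch induces in many cells, did not pass. The list test pointed up and passed (adjusted p = 7.9e-05, limma cameraPR), with adjusted p = 0.775 with an estimated correlation. The median was 0.08, or 0.04 after median centring, against a mean of 0.39. Without the 4 members that other lists also hold, Il2ra and Cd3g among them, the median was 0.07 and the test pointed down and did not pass (adjusted p = 0.676). Of 14 Wnt/beta-catenin target genes, Lef1 rose and Ccnd1 fell, also adjusted over the list alone, and the list did not pass (median -0.03, or -0.08 with replicate 1 alone or after renewed quantile normalization, adjusted p = 0.603). Axin2, a common reporter of this pathway, differed by 0.59 and did not pass.

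Of 14 cytokine and homing receptors, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.81 (adjusted p = 9.2e-13, and adjusted p = 0.729 with an estimated correlation). Il7r, Ccr4 (2.41), Il2rb (1.77) and Ccr7 (1.58) were among the risers, and Cd44, an adhesion receptor, fell by 0.87. Of 9 gamma delta and alternative T cell genes, 3 rose and 6 did not pass, also adjusted over the list alone. The gamma delta median was 0.54, or 0.34 with replicate 1 alone and 0.75 with replicate 2 alone (adjusted p = 5.1e-08, limma cameraPR, and adjusted p = 0.729 with an estimated correlation). Il17rb (1.94), a receptor of interleukin 17 family cytokines, and Cd163l1 (1.71) rose, as did Cpa3 (2.36), better known as a mast cell protease. Of 7 genes of the sort gates, Il2ra, Thy1 and Kit (1.54) rose and Flt3 fell by 0.91 (4 and 2 adjusted over the list alone). This list was set by the gate itself (median 0.72, adjusted p = 1.9e-29, and adjusted p = 0.729 with an estimated correlation).

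Interferon response genes moved together: of 16, 13 rose and 3 did not pass (15 adjusted over the list alone). Rtp4, Oasl2 (3.12), Ddx58 (2.88) and Usp18 (2.34) had the largest differences, and the median was 1.41 (adjusted p = 2.0e-60, and adjusted p = 0.729 with an estimated correlation). Of 25 stem and progenitor genes, 1 rose, 9 fell and 15 did not pass (8 and 13 adjusted over the list alone). Lmo2 (-2.10) and Mef2c (-1.87), transcriptional regulators of progenitors, fell, as did Hlf (-1.58) and Bcl11a (-1.47), while Cd34 differed by 0.14 and Hoxa9 by 0.53 without passing. The list was shifted down (median -0.62, adjusted p = 1.1e-05, and adjusted p = 0.729 with an estimated correlation). Of 26 myeloid genes, 3 rose, 7 fell and 16 did not pass (6 and 13 adjusted over the list alone). Ngp, Elane, Irf8 (-2.16), a transcription factor of macrophage and dendritic lineages, and Ctsg (-1.20) fell, while Adgre1, Mmp8 (2.53), a neutrophil collagenase, and Lyz2 (2.14), a lysozyme of macrophages and granulocytes, rose. The myeloid shift was downward (median -0.40, adjusted p = 0.0363, and adjusted p = 0.729 with an estimated correlation), and over genes above the median expression the list median was -0.08 and the test pointed up and did not pass (adjusted p = 0.133). Without genes of other lists the myeloid shift did not pass either (adjusted p = 0.0705). Beside it, 2 of 15 macrophage markers rose (7 and 1 fell adjusted over the list alone), with a median of 0.37 (0.19 with replicate 1 alone and 0.49 with replicate 2 alone).

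Lists of other cell types were as follows. Of 24 NK and innate lymphoid genes, Gzmb (2.18), Ccl5 (2.12) and Il2rb rose and Eomes fell by 1.58 (10 and 2 adjusted over the list alone). The NK median was 0.42, or 0.27 with replicate 1 alone and 0.51 with replicate 2 alone (adjusted p = 4.5e-04, limma cameraPR, and adjusted p = 0.747 with an estimated correlation). Of 19 stromal cell genes, 4 rose and 15 did not pass (7 adjusted over the list alone): Timp3 (3.75), an inhibitor of metalloproteinases, Thbs1 (3.12), thrombospondin, Bgn (2.25) and Fn1 (1.90). The stromal median was 0.39, or 0.25 with replicate 1 alone (adjusted p = 1.0e-12, and adjusted p = 0.729 with an estimated correlation), and Col1a1 (0.21) and Col3a1 (0.08), abundant collagens of stroma, did not pass. Of 15 mast cell, basophil, erythroid and megakaryocyte genes, Car2, Mcpt8 (-2.31) and Car1 (-1.74) fell and Cpa3 rose (2 rose and 4 fell adjusted over the list alone; median -0.09, or -0.17 after renewed quantile normalization, adjusted p = 0.00617, and adjusted p = 0.729 with an estimated correlation). Of 17 B lineage genes, Cd72 (0.96) rose and Cd79b (-2.39) fell (1 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.613). Its median was 0.07, or -0.01 after renewed quantile normalization, while its mean (-0.08) and test pointed down. Of 15 dendritic cell and MHC class II genes, Tcf4 (-0.99) fell (1 rose and 2 fell adjusted over the list alone; median -0.19, adjusted p = 0.345). The dendritic median was -0.46 with replicate 1 alone and 0.10 with replicate 2 alone. Of 17 immediate early and heat shock genes, Dusp1 (1.59) rose (2 adjusted over the list alone; median 0.33, adjusted p = 6.2e-04, and adjusted p = 0.729 with an estimated correlation). No gene of 26 cell cycle genes passed in limma, alone or over all genes, and 8 were lower at an unadjusted p under 0.05. The cell cycle median was -0.25, or -0.16 after renewed quantile normalization (adjusted p = 0.0025, and adjusted p = 0.729 with an estimated correlation), and the list did not pass over genes above the median expression (adjusted p = 0.111).

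**Figure D1:**
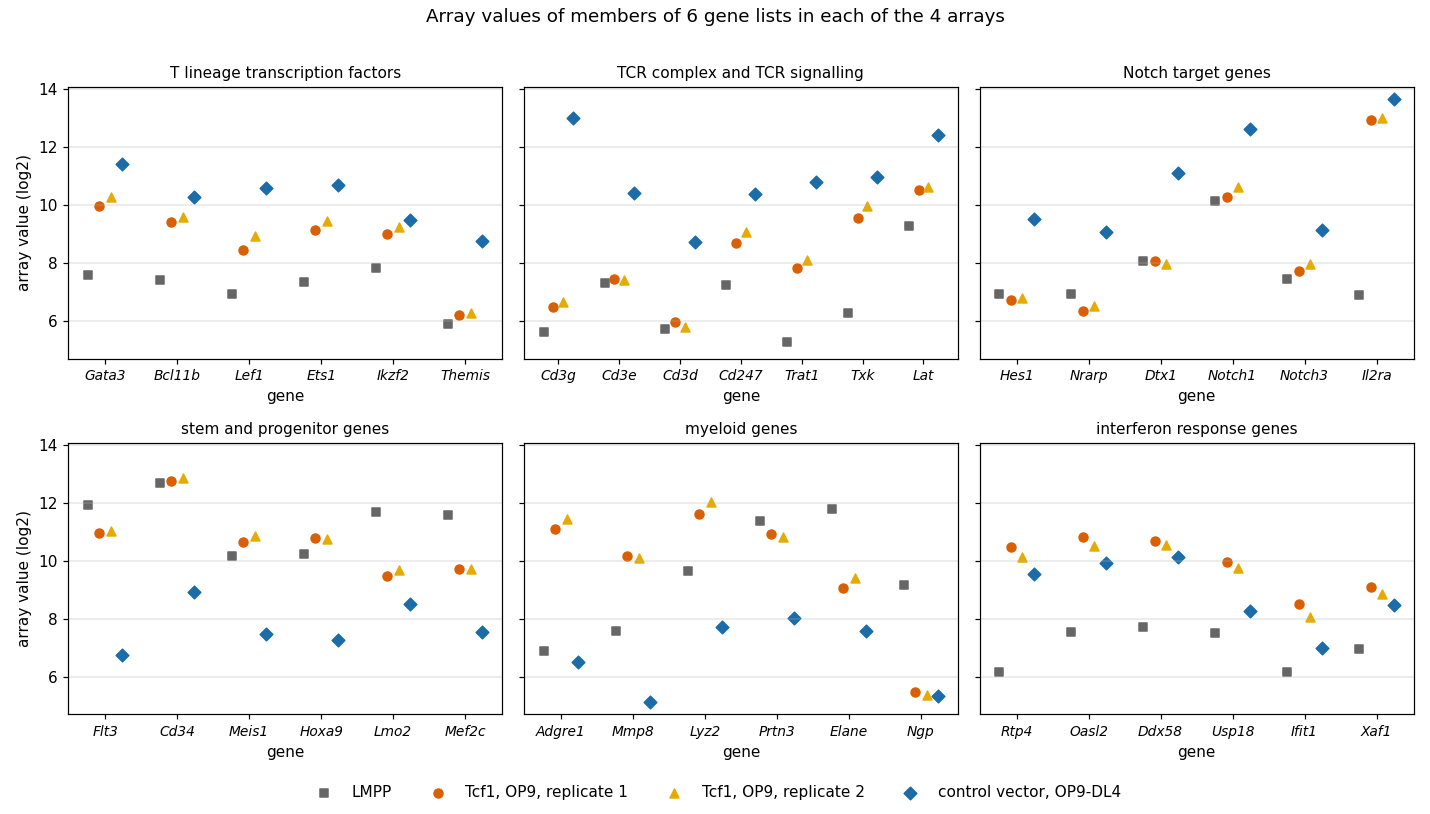
Array values on the log2 scale for members of 6 gene lists in the LMPP array (squares), Tcf1 replicate 1 (circles), Tcf1 replicate 2 (triangles) and the control array (diamonds), with each point 1 array. Gata3 read 7.58 in LMPPs and 11.42 in control cells with both Tcf1 arrays between, while Hes1 read 6.73 and 6.79 in the Tcf1 arrays, 6.94 in LMPPs and 9.52 in control cells.

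In all, 610 of 19938 genes passed between Tcf1 cells and LMPPs (limma, Benjamini-Hochberg adjusted), 349 higher (57.2%) and 261 lower, and 2900 had an unadjusted p under 0.05. The smallest fold that passed was 1.78. At least 2-fold apart were 577 genes, 356 higher and 221 lower, but the balance rested on the replicate: 70.6% were higher with replicate 2 alone and 48.3% with replicate 1 alone. The test had 1 residual degree of freedom, from the Tcf1 pair, and took the single arrays to vary as that pair did. The count moved to 1456 after median centring (607 higher, 849 lower, so 41.7% higher), to 1196 over genes above the 25th percentile of expression, to 12 with an unmoderated test and to 0 over all 35399 probe sets, where 3317 had an unadjusted p under 0.05 in limma.

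Tcf1 cells were next compared with control cells to ask how T lineage cells obtained with Tcf1 differed from those obtained with Notch ligand. Lower in Tcf1 cells were 13 of 24 T cell receptor, 5 of 9 recombination and 7 of 16 Notch target genes, and higher were 11 of 25 progenitor and 11 of 26 myeloid genes. For each of these lists as a whole, adjusted p = 0.586 with an estimated correlation (limma camera), a test on 1 residual degree of freedom that no list passed. Cd3g, a chain of the CD3 complex, differed by -6.44 (SE 0.17, adjusted p = 7.3e-05, limma), with 6.56 ± 0.12 (SD, n = 2) in Tcf1 cells and 13.001 in the control array. Rag1, a recombinase of antigen receptor genes, differed by -3.22 (SE 0.17), and the Notch target Hes1 by -2.77 (SE 0.16). Flt3, the cytokine receptor by which LMPPs were sorted, was higher by 4.24 (SE 0.16), and Mmp8 was higher by 4.99 (SE 0.16). Both Tcf1 arrays lay on the same side of the control array for each of these genes.

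The genes lower in Tcf1 cells by the most were, after Cd3g, Khdc1a (-4.71), Gzma (-3.91), a cytotoxic granule protease, Nqo1 (-3.82), a quinone oxidoreductase, Ly6d (-3.63), a lymphoid surface antigen, Fbp1 (-3.62), an enzyme of gluconeogenesis, Blk (-3.38), a Src family kinase, Rag1, Dusp4 (-3.17), a MAP kinase phosphatase, and Angpt1 (-3.15). Those higher by the most were, after Mmp8, Adgre1 (4.76), Cd74 (4.53), the invariant chain of MHC class II, Cybb (4.39), a subunit of the phagocyte NADPH oxidase, Ly6a2 (4.37), Flt3, Wfdc17 (4.11), Mgl2 (4.10), a macrophage lectin, Lyz2 (4.09) and H2-Aa (4.06), an MHC class II chain. Ly6a2 has close relatives in its family, so its signal could be shared. H2-Aa differed by 1.37 between the Tcf1 replicates. Standard errors of these 20 differences ran from 0.16 for Gzma to 0.48 for H2-Aa. The sort markers Thy1 (-0.52, adjusted p = 0.187, limma) and Il2ra (-0.69, adjusted p = 0.0762, limma) read lower in both Tcf1 arrays but did not pass over all genes.

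Of 22 T lineage transcription factors, 8 were lower in Tcf1 cells and 14 did not pass (1 higher and 13 lower adjusted over the list alone). Themis (-2.53), Lef1 (-1.91), Ets1 (-1.41), Tox (-1.40) and Gata3 (-1.30) were lower, and Bcl11b differed by -0.78 without passing (adjusted p = 0.0593, limma). The list was shifted down (median -0.55, adjusted p = 4.8e-13, and adjusted p = 0.635 with an estimated correlation). Of 24 T cell receptor genes, 13 were lower, Cd96 was higher (1.21) and 10 did not pass (2 higher and 17 lower adjusted over the list alone). Cd3e (-2.98), Cd3d (-2.86), Trat1 (-2.82) and the kinase Prkcq (-2.72) were lower, with a list median of -0.96 (adjusted p = 5.4e-37). Of 9 recombination genes, 5 were lower (6 adjusted over the list alone), among them Rag2 (-2.26) and Dntt (-1.90), which adds bases at junctions, with a median of -1.15 (adjusted p = 9.7e-16). Of 16 Notch target genes, 7 were lower and 9 did not pass (10 lower adjusted over the list alone). Dtx1 (-3.08), Nrarp (-2.65) and Notch1 (-2.18) were lower beside Hes1, while Il2ra, Myc (-0.09) and Igf1r (-0.03) did not pass, with a list median of -0.66 (adjusted p = 1.5e-33). Of 9 gamma delta and alternative T cell genes, 4 were lower (1 higher and 6 lower adjusted over the list alone), among them Cd163l1 (-2.02) and Il17rb (-2.01), with a median of -0.85 (adjusted p = 6.5e-13). For the T cell receptor, recombination, Notch and gamma delta lists, adjusted p = 0.586 with an estimated correlation.

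Of 25 stem and progenitor genes, 11 were higher in Tcf1 cells and 14 did not pass (12 higher and 2 lower adjusted over the list alone). Cd34 (3.90), a progenitor surface protein, Hoxa9 (3.49) and Meis1 (3.29), homeobox regulators of progenitors, and Spi1 (2.01), a regulator of myeloid and early lymphoid cells, were higher, with a list median of 0.39 (adjusted p = 2.7e-30). Of 26 myeloid genes, 11 were higher and 15 did not pass (16 higher adjusted over the list alone). Besides Mmp8, Adgre1 and Lyz2, the shared cytokine receptor chain Csf2rb (2.96) and the granule proteases Prtn3 (2.82) and Elane (1.66) were higher, with a median of 0.70 (adjusted p = 7.9e-45). Of 15 dendritic cell and MHC class II genes, H2-Aa, H2-Ab1 (3.54), H2-Eb1 (1.98) and Cd74 were higher (5 adjusted over the list alone), with a median of 0.42 (adjusted p = 3.8e-06). Macrophage markers moved with these groups: 7 of 15 were higher (12 adjusted over the list alone), with a median of 0.93, and C1qb (2.24) and Mrc1 (2.27) were among them. Of 16 interferon response genes, 6 were higher (12 adjusted over the list alone), among them Usp18 (1.58), Oas1a (1.46) and Ifit1 (1.28), with a median of 0.71 (adjusted p = 5.9e-09). Of 19 stromal cell genes, Fn1 (1.80) and Bgn (1.52) were higher (4 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.00375), while Timp3 differed by 0.06 and Thbs1 by 0.58 without passing. For the progenitor, myeloid, dendritic, interferon and stromal lists, adjusted p = 0.586 with an estimated correlation.

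The sort gate genes gave Flt3 as the single member past the test (2 higher and 2 lower adjusted over the list alone). Their median was -0.17 while the mean (0.50) and the test pointed up (adjusted p = 0.00177, and adjusted p = 0.968 with an estimated correlation), and without the 4 members of other lists the test pointed down and did not pass (median -0.22, adjusted p = 0.634). Other lists did not pass over all genes, but the Wnt/beta-catenin (median -0.43, adjusted p = 0.0335), B lineage (median -0.17, adjusted p = 0.00222) and mast cell (median -1.02, adjusted p = 4.5e-04) lists passed lower over genes above the median expression. With an estimated correlation, run over all genes only, their adjusted p was 0.872, 0.968 and 0.872. Of 24 NK and innate lymphoid genes, Ccl5 (1.93), Tyrobp (1.86), Klrd1 (1.85) and Xcl1 (1.01) were higher and Gzma, Nkg7 (-1.45), Zbtb16 (-1.36) and Il18r1 (-1.22) lower (9 and 4 adjusted over the list alone). The NK median was 0.32, or 0.15 with replicate 1 alone and 0.49 with replicate 2 alone, and the list did not pass (adjusted p = 0.385, limma cameraPR). Of 14 cytokine and homing receptors, Cd44 (1.55) was higher and Itgae (-1.31) and Ccr4 (-1.25) lower (5 and 3 adjusted over the list alone; median 0.17, or 0.09 after renewed quantile normalization, adjusted p = 0.385). Of 14 Wnt/beta-catenin target genes, Lef1 and Apcdd1 (-0.92) were lower, also adjusted over the list alone (median -0.01, or -0.06 with replicate 1 alone and -0.08 after renewed quantile normalization, adjusted p = 0.142). Of 17 B lineage genes, Blk and Cd79b (-1.53) were lower (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.208), with a median of 0.06 (-0.02 after renewed quantile normalization) but a mean of -0.18 and a test that pointed down. Of 15 mast cell, basophil, erythroid and megakaryocyte genes, Car2 (-1.20) and Mcpt8 (-1.83) were lower (3 adjusted over the list alone; adjusted p = 0.229), with a median of 0.06 (-0.0036 after renewed quantile normalization and -0.06 with replicate 2 alone) but a mean of -0.19 and a test that pointed down. Of 17 immediate early and heat shock genes, Atf3 (0.88) and Zfp36 (0.82) were higher and Jun (-1.14) lower (2 and 2 adjusted over the list alone; median 0.17, or -0.00199 with replicate 1 alone, adjusted p = 0.697). No gene of 26 cell cycle genes passed in limma, alone or over all genes, with 1 lower at an unadjusted p under 0.05 (adjusted p of the list 0.888). The cell cycle median was -0.00345, or 0.08 after renewed quantile normalization and 0.06 with replicate 2 alone.

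In all, 874 of 19938 genes passed between Tcf1 and control cells (limma, Benjamini-Hochberg adjusted), 378 higher (43.2%) and 496 lower, and 2809 had an unadjusted p under 0.05. The smallest fold that passed was 1.70. At least 2-fold apart were 756 genes, 353 higher and 403 lower, and 58.1% were higher with replicate 2 alone against 36.1% with replicate 1 alone. The control group was 1 array, and the spread again came from the Tcf1 pair. The count moved to 1646 after median centring, to 1437 over genes above the 25th percentile of expression, to 12 with an unmoderated test and to 0 over all probe sets, where 3702 had an unadjusted p under 0.05 in limma.

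Control cells were compared with LMPPs to show the differences of T lineage cells grown with Notch ligand. With 1 array against 1 array there was no replicate check and no p-value. Cd3g was higher by 7.38, Trgv1 by 7.001, Il2ra by 6.75, Khdc1a by 5.59, Fam20a by 5.52, Trat1 by 5.51, Rasgrp1 by 5.14, Ctla4, an inhibitory T cell receptor, by 5.07, Thy1 by 4.85 and Glp1r by 4.72. Flt3 was lower at -5.16, Cd74 at -4.99, Mpeg1, a macrophage pore-forming protein, at -4.80, Adgrl4 at -4.80, Gapt at -4.40, H2-Aa at -4.31, Ms4a3 at -4.25, Gem at -4.21, Elane at -4.19 and Gatm, an enzyme of creatine synthesis, at -4.19. At least 2-fold apart were 1102 genes, 632 higher and 470 lower in control cells.

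List medians of the control array against the LMPP array were placed among 10000 random lists of equal size matched on mean expression. The T lineage transcription factors (0.70), T cell receptor genes (0.95), recombination genes (1.06), Notch target genes (0.70), cytokine and homing receptors (0.71), interferon response genes (0.84), gamma delta genes (1.27) and sort gate genes (0.94) lay above every random list drawn (percentile 100). At least 2-fold higher in control cells were 12 of the 24 T cell receptor genes, among them Cd3e (3.09) and Lat (3.11), 5 of 9 recombination genes, among them Rag1 (3.74), and 7 of 16 Notch target genes, among them Dtx1 (3.03) and Hes1 (2.58), while Cd96 (-3.31) of the T cell receptor list and Dtx4 (-1.41) of the Notch list were at least 2-fold lower. The stem and progenitor genes (-1.27), myeloid genes (-1.32) and dendritic cell and MHC class II genes (-0.88) lay below every random list drawn (percentile 0). At least 2-fold lower were 14 of 25 progenitor genes, among them Mef2c (-4.02) and Cd34 (-3.75), against Kit (1.71) and Erg (1.13) at least 2-fold higher, and 17 of 26 myeloid genes, among them Prtn3 (-3.33) and Mpo (-2.69), the myeloperoxidase of granules. The NK and innate lymphoid (0.06, percentile 92.6), stromal (0.09, percentile 95.1) and immediate early and heat shock (0.21, percentile 98.5) medians lay in the upper part of the random lists. The Wnt/beta-catenin (-0.02, percentile 40.0) and B lineage (-0.03, percentile 28.2) medians lay near their middle. The cell cycle (-0.25, percentile 1.81), mast cell and erythroid (-0.16, percentile 0.57) and macrophage marker (-0.22, percentile 1.53) medians lay low. At least 2-fold apart were Blk (3.31) in the B lineage list, Lef1 (3.66) and Ccnd1 (-3.11) in the Wnt/beta-catenin list, Car2 (-2.44), Car1 (-1.92) and Cpa3 (3.21), among others, in the mast cell and erythroid list, and Csf1r (-1.67), among others, in the macrophage list.

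The differences of Tcf1 and of control cells from the same LMPP array were set side by side to ask how far both routes to T lineage cells shared changes. Of the 349 genes that rose in Tcf1 cells, 202 (57.9%) were also at least 2-fold higher in control cells than in LMPPs, among them Il2ra, Rasgrp1, Gata3 and Timp3. Of the 261 genes that fell, 160 (61.3%) were at least 2-fold lower in control cells, among them Adgrl4, Ngp and Gem. Both sides of these shares rest on the same LMPP array: by a 2-fold minimum in place of the test they were 54.2% and 64.7%, and 33.9% and 35.4% in simulated unchanged groups, in which 1.21 and 1.27 genes per draw reached 2-fold in Tcf1 cells. From the other side, 343 of the 632 genes higher in control cells than in LMPPs were past the test lower in Tcf1 cells than in control cells, among them Cd3g, Rag1 and Hes1. Of the 470 genes lower in control cells than in LMPPs, 194 were past the test higher in Tcf1 cells than in control cells, among them Flt3, Cd34, Hoxa9 and Cd74. Both sides of these counts rest on the same control array: by a 2-fold minimum in place of the test they were 307 (48.6%) and 182 (38.7%), against 0.37 (11.8%) and 0.33 (12.0%) per draw in simulated unchanged groups.

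**Figure D2:**
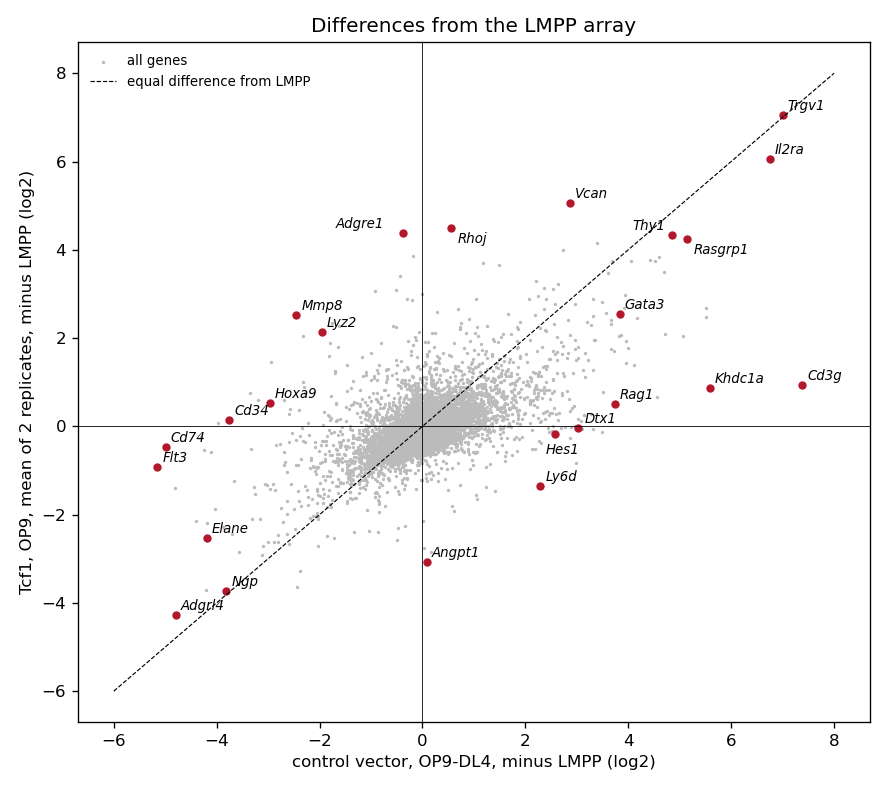
Log2 difference of the Tcf1 mean (2 arrays) from the LMPP array, against the log2 difference of the control array from the LMPP array, with each point a gene and named genes in red; the dashed line marks equal differences. Trgv1 (7.04 and 7.001) lies on the line, Cd3g (0.94 and 7.38) far below it, and Mmp8 (2.53 and -2.45) in the quadrant of opposite signs.

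Across genes, the differences of Tcf1 and of control cells from LMPPs correlated with r = 0.606 and a rank correlation of 0.548, where genes are not independent replicates. Unchanged groups simulated against the same LMPP array (100 draws) gave r = 0.577 and a rank correlation of 0.557. The observed rank correlation was not above the simulated value. In unchanged groups these correlations come from the shared array alone, whatever the overall size of the spread. They therefore cannot decide how far changes were shared. The covariance was 0.137 against 0.0216 simulated, a difference of 0.115. At least 2-fold higher in both were 193 genes, with 11.3 expected from independent lists and 0.44 simulated, and 143 were lower in both, with 5.21 expected and 0.37 simulated. The balance rested on the replicate: 153 higher and 172 lower with replicate 1 alone, against 231 and 129 with replicate 2 alone. Another 24 genes differed from LMPPs in opposite directions, with 0 simulated. The LMPP reference was 1 array and could not be split, so part of the excess may come from it.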

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

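The tests of progenitor expression, with its simulated share, and of a mixture of cells were chosen after the results were seen, and the second mixture test after the value of the first. The 19 genes at least 2-fold higher than LMPPs in Tcf1 cells and at least 2-fold lower in control cells were singled out because the groups moved in opposite directions: Adgrg6, Atp11a, C3ar1, Ccl22, Cd33, Cd80, Ctss, Cybb, Dab2, Fcgr2b, Hp, Itgb5, Ly6a2, Lyz2, Mgl2, Mmp8, Mrc1, Ms4a6c and Tmem178. Another 5 genes went the other way: Ctse, Fmnl2, Gimap6, Ly6d and Slc14a1. The difference between the groups was set by this selection and was not tested further. Lyz2 differed from LMPPs by 2.14 in Tcf1 cells and -1.95 in control cells, and Ly6d by -1.34 and 2.29.

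Of 26 myeloid genes, 11 were higher in Tcf1 cells than in control cells and 15 did not pass. The adjusted p of the list was 7.9e-45 by limma cameraPR at the preset correlation. It was 0.586 with an estimated correlation, which rested on 1 residual degree of freedom. A narrower signal range of the first Tcf1 array was argued against: replicate 2 alone, quantile normalized again, kept 96.7% of the myeloid median (0.68 against 0.70), while macrophages carried through the sort may contribute, since the median of 15 macrophage markers was 0.926 with 93.3% higher, short of the 1 set for this cause, and was 0.79 with replicate 1 alone and past that limit with replicate 2 alone (1.06). C1qa (0.16), Apoe (0.04), Ctsd (-0.08) and Itgam (0.53), which encodes the gated Mac1, did not pass, and Csf1r, Cd68, Cd14 and Itgam belong to both lists. Progenitor expression that was not lost was left open by its test: in LMPPs 172 of 307 genes (56.0%) were at least 2-fold over control cells too, but both of its sides use the same control array, and by a 2-fold minimum alone it was 51.6% against 26.6% in simulated unchanged groups, and 92 of the 307 were also past the test above LMPPs, which this explanation alone does not give. These explanations cannot be told apart without single cells, and the difference in vector and in stroma stays open as untested.

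Thbs1 and Timp3, known in stroma, were higher in Tcf1 cells than in LMPPs. Stromal cells carried through the sort may be a source: the 17 other stromal genes had median differences from LMPPs of 0.24 and 0.28 in the Tcf1 arrays and 0.08 in the control array. The highest of these, 0.282, lay between the 1 set for this cause and the limit of 0.2 set against it for all 3 arrays. In the control array, Timp3 and Thbs1 were 3.68 and 2.54 above LMPPs while the median of the 17 others lay under that limit; in Tcf1 cells Bgn (2.25) and Fn1 (1.90) rose and were higher than in control cells, and the collagens Col1a1 (0.21) and Col3a1 (0.08) did not pass. Expression by the T lineage cells themselves was not tested.

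T lineage genes were unevenly lower in Tcf1 cells than in control cells. If Tcf1 samples were a mixture of control-like and LMPP-like cells, the 194 genes at least 4-fold higher in control cells than in LMPPs would imply a single share of control-like cells. The median share was 22.2%, and 44.8% of genes (binomial SE 3.57) lay within 15 points of it. That is under the limit of 50 but too near it to decide. The binomial SE takes the genes as independent, which genes of the same arrays are not, so it may be too small. In the second test, chosen after that value, 48 genes implied under 10% in both replicates and 32 over 50% in both, the smaller set being 16.5%, which argues against a mixture of exactly these 2 measured profiles. Each profile rests on 1 array, so a mixture with other T lineage cells stays open, and the effect of vector and stroma was not tested.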

How the results depend on the processing

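The stretching of replicate 1 and the renewed normalization for the lists were chosen after the data were seen; the other alternatives were planned. Genes passing between Tcf1 cells and LMPPs (610) numbered 936 with a mean-variance trend, 1196 above the 25th percentile, 1189 above the median, 1456 after median centring, 1039 at adjusted p under 0.1, 12 unmoderated and 0 over all probe sets, where 3317 had an unadjusted p under 0.05 in limma. With 3 T lineage arrays as a single group 3 passed. Between Tcf1 and control cells (874) they numbered 1437 above the 25th percentile, 1646 after median centring, 12 unmoderated and 0 over all probe sets, where 3702 had an unadjusted p under 0.05 in limma. The 12 were the genes with equal values in both Tcf1 arrays. Robust priors (612 and 881), renewed quantile normalization (726 and 1006), the mean of probe sets (674 and 963) and stretching (565 and 814) stayed within 1.5 times. At 1.5-fold the counts of genes were 1623 (Tcf1 against LMPP), 1784 (Tcf1 against control) and 2694 (control against LMPP), and at 3-fold 226, 291 and 485. Leaving out a Tcf1 replicate gave 605 to 637 and 749 to 848 genes at least 2-fold apart, a correlation of 0.555 to 0.612 and an overlap of 325 to 360 genes. The ratio of array distances was 2.66 above the median. With an estimated correlation 0 lists passed, down from 14 against LMPPs and 11 against control cells; by construction it rested on 1 residual degree of freedom. The direction of the list test turned without passing for myeloid genes above the median (adjusted p = 0.133, Tcf1 against LMPP) and, without genes of other lists, for Notch targets (0.676, Tcf1 against LMPP) and sort gate genes (0.634, Tcf1 against control). Except where the construction is named, the cause was not tested. In 307 alternatives other than leaving out a replicate, the direction and the side of the threshold (or the size) were kept. Of these, 161 were named genes under the mean of probe sets. That setting leaves the value of a gene with a single probe set unchanged, and only 999 of 19938 genes had several. Another 11 were lists that did not pass, tested with an estimated correlation, under which no list passed. Much of this count was therefore fixed in advance. In 36 alternatives for single genes and lists, a call was ended, made or turned. Among them were the Wnt/beta-catenin (0.0335), B lineage (0.00222) and mast cell lists (4.5e-04), which passed above the median for Tcf1 against control cells. Without a replicate, 328 named gene values and 72 list medians were recomputed as values with no test, since no residual degree of freedom was left, and 0 of those called by limma changed sign. Genes named by the largest differences were chosen with both Tcf1 arrays on the same side, so their sign could not change. For other called genes a change was unlikely from the start, because the test used the spread of the same pair. No paired analysis was possible because only the Tcf1 group carries replicate numbers. Signal over background could not be measured without detection calls, which limits statements on dim genes.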

Other observations

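All tests in this part were chosen after the values were seen. Of 8 measured Gimap genes, a family of lymphocyte GTPases, 7 were lower in Tcf1 than in control cells, with Gimap6 (-2.71), Gimap5 (-2.67), Gimap9 (-2.40) and Gimap4 (-2.21) the largest differences and a family median of -1.87. Control cells had a family median 1.32 above LMPPs. Of 10 Hoxa genes, 6 were higher in Tcf1 than in control cells (median 1.11). Of 19 Ms4a genes, 7 rose from LMPPs to Tcf1 cells, among them Ms4a6b (3.48) and Ms4a6d (3.06), and 6 were higher than in control cells, among them Ms4a6d (3.99) and Ms4a4c (3.83). Of 9 Slfn genes, 4 rose, with Slfn5 at 2.88. Of 8 Gbp genes, 4 rose, with Gbp11 at 2.69, and 4 were lower than in control cells. The medians of these families for Tcf1 cells against LMPPs and against control cells kept their sign under renewed quantile normalization and median centring. The Hoxb, Clec, MHC class II and T cell receptor segment families were examined too, and not all kept it. Against control cells, the Hoxb median of 0.01 turned to -0.06 and -0.03. Against LMPPs, renewed quantile normalization turned the MHC class II median from -0.10 to 0.02. It also turned that of the alpha beta receptor segments from 0.06 to -0.0030. The median of control cells against LMPPs was not recomputed.

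In Tcf1 cells, 86 genes were at least 2-fold higher than in both other groups and past both limma tests, among them Adgre1, Rhoj, F13a1, Vcan and Tgfbi (3.08 over LMPPs and 3.59 over control cells). Another 31 were at least 2-fold lower than in both, among them Angpt1, Scin, Nrp1, Ly6d and Car2. Both tests use the same 2 Tcf1 arrays and their spread, so passing both is not independent support. Between the Tcf1 replicates, 36 of the 65 genes at least 2-fold apart were higher in replicate 2, among them Glp1r (1.76), H2-Aa (1.37), H2-Ab1 (1.31) and Irf4 (1.28), and 29 in replicate 1, among them Mir680-2 (-2.80).

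Of 13610 probe sets without a single gene name, 706 (5.19%) were at least 2-fold apart between the Tcf1 replicates, against 92 (0.422%) of the 21789 with a name. Both Tcf1 arrays lay at least 2-fold from LMPPs at 161 of them and from control cells at 225.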
